A study of Mus musculus with 72 samples.

How the data were processed

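Gene expression was measured on oligonucleotide arrays in whole blood of female Balb/c mice that drank water with 0, 5 or 50 µg/mL of lead acetate trihydrate for 2 weeks and then plain water for 2 weeks. Blood was drawn from the submandibular vein at the end of the exposure and again at the end of the recovery. Per the labels' protocols, blood was stabilised in RNAprotect tubes, RNA was isolated with the RNeasy Protect Animal Blood kit, globin transcripts were depleted with GLOBINclear, and the RNA was amplified and biotin-labelled with the MessageAmp Premier kit. The 72 arrays fall into 6 groups by dose and collection: 7 control, 15 low-dose and 15 high-dose arrays after exposure, and 7, 15 and 13 after recovery. Groups and replicate numbers came from the sample titles. The labels say that all exposed mice were bled after exposure. They do not say whether the 7 control mice of the recovery collection were those of the first.

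The deposited values are on a log2 scale and were normalized by robust multi-array averaging (RMA), per the submitters' processing notes. The RMA software, its version and its background step are not given in the sources used here. The lowest deposited value was 0.410 and the highest 14.1, and the lowest values lie below those that RMA usually gives, so the exact variant stays unknown. Array medians lay between 4.05 and 4.22. Probe sets were named through a table of platform annotation. Of 45101 probe sets, 64 were array controls, 34958 had exactly 1 gene symbol, 932 had several and 9211 were not listed there and are unnamed here. Through the gene identifier, 34754 probe sets were matched to a table of current mouse genes, and 0 symbols changed. No gene was named from a probe set with several symbols.

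All statistics were computed from the deposited values without a further normalization. A probe set was kept when it lay above the median of all deposited values, 4.14, in at least 7 arrays, the size of the smallest group. Of the 1-symbol probe sets, 21054 passed. Each gene was represented by the probe set with the highest mean over the 72 arrays, which gave 12589 tested genes of 18194 with any 1-symbol probe set. Group means were fitted to all 72 arrays with limma 3.58.1 (with statmod 1.5.0, in R 4.3.3), so that the comparisons shared 1 estimate of each gene's spread with 66 residual degrees of freedom, and tested with empirical Bayes moderation. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were counted. Values of single groups are means ± SD, and log2 differences are given ± SE. Where the number of arrays beyond another group is given, it counts the arrays of the first group, the treated or the recovery group, that lay outside the range of the group they were compared with, in the direction of the difference.

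The comparisons were high dose against control, low dose against control and high against low dose, each after exposure and after recovery. Recovery was compared with exposure within each of the 3 dose groups, and the difference between the dose effect after recovery and that after exposure was tested as an interaction for each dose. The overlap of the calls of both doses, which share their controls, was set beside 100 simulations of unchanged groups against the same controls and beside splits of the 7 controls into 3 and 4.

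For gene groups, 28 lists were written: heme synthesis, iron handling, lead target proteins, reticulocyte and erythroid genes, globin genes, metallothionein and metal transport, antioxidant and Nrf2 targets, heat shock and unfolded protein response, interferon response, inflammation and NF-kappaB targets, immediate early genes, glucocorticoid response, circadian clock, cell cycle, p53 and DNA damage, ribosomal proteins, oxidative phosphorylation, proteasome, MHC class II and antigen presentation, markers of neutrophils, B cells, T cells, NK and cytotoxic cells, monocytes, platelets and megakaryocytes, eosinophils and basophils, and plasma cells, and genes of facial skin, muscle and salivary gland, tissues that the bleeding site could add. Between 5 and 38 members of each were measured, and 12 genes stood in 2 lists. Each list was tested against all other genes with camera at a preset correlation between genes of 0.01, and adjusted over the 28 lists. The test was repeated with a correlation estimated for each list, and with fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes. Calls within a list were also adjusted over the list alone.

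Named genes followed a rule. In comparisons with control these were the 10 highest and the 10 lowest log2 differences among the genes past the threshold, in other comparisons the 5 highest and 5 lowest. Where fewer than 5 genes passed, the 5 with the smallest p were named as not past the threshold. Up to 4 members with the smallest p were named for each list described. Clone names, gene models and accessions, 691 symbols, were passed over. In comparisons with control Alad, Alas2, Fech, Nt5c3, Hmox1, Tfrc, Mt1 and Mt2 were named whatever their result; Hmox1 was not among the tested genes. The comparisons, lists, naming rule, main test and most alternatives were fixed before the data were examined.

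Array quality was compared with control in each phase by exact permutation tests, two-sided, on 6 measures: the 3' minus 5' difference of the Gapdh and of the beta-actin control probe sets, which rises as RNA becomes shorter or is copied less far from its 3' end, the mean of the poly-A spike-in probe sets, the mean of the hybridisation spike-in probe sets, the interquartile range of each array's relative log expression, and the mean of the globin genes. These 24 tests were adjusted together. 18S ribosomal RNA was compared with control later, in 4 tests adjusted together. The other 5 comparisons were tested on the same measures and on 18S ribosomal RNA after the data were examined, 35 tests adjusted together, with 100000 resamples where both groups held more than 10 arrays. No scan date, plate or other batch was given in the labels, so no batch term could be fitted. The number of arrays limits the precision of every comparison with control.

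Alternatives were a stricter and no filter on dim probe sets, the mean of a gene's probe sets, each probe set tested by itself, probe sets with possible cross-hybridisation left out, quantile, median-centred and cyclic loess rescaling, array weights, arrays with a wide spread of relative log expression left out, trended and robust moderation, fits of only the groups compared, the replicate number as a block, a 1.5-fold minimum, and the means of 6 blood cell marker lists as covariates. Later additions are named with their effects in the closing section. The steps were tested on simulated data in which 100 of the 12589 genes were changed by each of 2 fold sizes. At 1.5-fold the share of changed genes recovered was 96% for high dose against control and 94% for low dose against control after exposure, 95% and 99% after recovery, and 89% and 82% for the interactions of the high and the low dose. At 2-fold it was 100% for high dose against control and 99% for low dose against control after exposure. A shifted list was found in each comparison, with 0 of the 27 other lists called. The simulated genes were drawn independently of each other, so this could not show false list calls that arise where genes are correlated.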

Results

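Whole-blood transcript levels were compared between mice given lead (Pb) in drinking water at 5 µg/mL (low dose) or 50 µg/mL (high dose) and control mice, after 2 weeks of exposure and after 2 further weeks on plain water. The design addresses which blood transcripts differ with Pb exposure and whether they still differ after it ends. After exposure 7 control, 15 low-dose and 15 high-dose arrays were measured, and after recovery 7, 15 and 13. Each array was a separate blood sample, and exposed mice were bled at both collections, so p-values measure the spread between these samples and treat the collections as independent. Arrays correlated between 0.958 and 0.995 across probe sets, with a median of 0.992 within groups and 0.986 between the collections, and 0 pairs of arrays were identical. The median log2 difference over all genes lay between -0.03 and 0.01 in every comparison. For gene lists, "list p" is the adjusted p of camera at its preset correlation.

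After exposure to the high dose, 3 genes were higher than in controls. Hspa1b, an inducible Hsp70 heat shock chaperone, rose by 1.93 ± 0.20 on the log2 scale, from 4.15 ± 0.34 (SD, n = 7) in controls to 6.08 ± 0.79 (SD, n = 15). All 15 high-dose arrays lay above every control array (limma, adjusted p = 5.56e-11). Dnajb1, an Hsp40 co-chaperone of Hsp70, rose by 0.64 ± 0.12, with 14 of 15 arrays above every control (adjusted p = 0.00358). Slc12a2, a sodium, potassium and chloride cotransporter, rose by 0.55 ± 0.11, from 5.75 ± 0.24 (SD, n = 7) to 6.30 ± 0.22 (SD, n = 15), with 13 arrays above every control (adjusted p = 0.00737). Its other probe sets, of mean signals 2.46 and 3.75, gave 0.26 and 0.21. Next in order of p, and not past the threshold, were the anticoagulant receptor gene Thbd (0.45) and Ccdc117 (0.39), both at an adjusted p of 0.0511.

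Among 12589 genes, 3 were higher and 0 lower at the high dose after exposure; 1193 genes had an unadjusted p under 0.05, where 629 would do so by chance. The split depended on scaling: 30 of 75 called genes were higher after quantile normalization, 27 of 36 after centring and 38 of 68 after cyclic loess. The count was 26 without control replicate 6 and 5 without control replicate 7. Cell marker means as covariates raised it to 195, 18S ribosomal RNA as a covariate raised it to 15, and the 3' to 5' covariates left 1.

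Lists of erythroid, cytotoxic and glucocorticoid response genes lay higher, and lymphocyte and translation genes lower, at the high dose after exposure. None of these 15 calls held: the interferon list had adjusted p = 0.643 with an estimated correlation and each other list adjusted p = 0.529 with an estimated correlation, and by fry 0 lists passed, the smallest adjusted p being 0.389. Of 33 reticulocyte and erythroid genes 30 were higher, none past the threshold by itself (Add2 0.42, Car1 0.30, Gata1 0.22, list p = 6.37e-07). All 5 globin genes were higher (Hbb-bh1 0.41, 1 gene adjusted over the list alone, list p = 0.0224), as were 9 of 13 heme synthesis genes (0.0285). Higher too were 13 of 18 NK and cytotoxic genes (0.000618), 23 of 36 interferon genes (0.0285) and 14 of 23 monocyte genes (Fcgr4 0.43, 3 adjusted over the list alone, 0.0131). So were 12 of 18 glucocorticoid genes (5 adjusted over the list alone, 0.000267), 10 of 15 circadian genes (1 adjusted over the list alone, 0.0285) and 22 of 30 cell cycle genes (1 lower adjusted over the list alone, 0.0285). Lower were 28 of 29 ribosomal protein genes (Rpl19 -0.16, list p = 5.1e-07), 25 of 29 proteasome genes (Psmb7 -0.35, 0.000267) and 31 of 38 oxidative phosphorylation genes (0.00288). Also lower were 22 of 24 B cell markers (Cr2 -0.41, Cd22 -0.33, 0.000172), 24 of 26 T cell markers (Cd27 -0.33, 0.000381) and 16 of 18 MHC class II genes (Cd74 -0.32, 0.00249). Where no count is given, 0 members passed adjusted over the list alone. The cell cycle and globin calls were lost under each rescaling (0.082 and 0.0592 after quantile normalization). The heme call was lost after quantile normalization (0.109) and the interferon call after centring (0.0547), and no called list turned direction.

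The heat shock list as a whole was not shifted at the high dose (26 measured, camera adjusted p = 0.0798), with 2 genes higher over all genes and 5 higher and 3 lower adjusted over the list alone. Its median was -0.04, while its mean of 0.09 and the test pointed upward. Dnaja1 (0.48, adjusted p = 0.0533) and Hsph1 (0.52, 0.0552), further chaperone genes, were not past the threshold. Immediate early genes were not shifted either (25 measured, 0.197, median -0.02, mean 0.04), with 3 higher adjusted over the list alone. Fos was 0.80 (0.0552), Dusp1 0.61 (0.0955), Cxcr4 0.62 (0.122) and the clock and glucocorticoid target Per1 0.31 (0.103). The remaining lists did not pass: lead target proteins (0.0922), platelet (0.128), eosinophil and basophil (0.128), NF-kappaB targets (0.365), metallothionein (0.407), antioxidant (0.595), p53 (0.676), neutrophil (0.773), facial tissue (0.773), iron handling (0.968) and plasma cell (0.968). Of these, the iron, metallothionein, antioxidant, NF-kappaB, p53, plasma cell and facial lists had a median, mean and test that differed in sign. Enzymes of heme synthesis known as Pb targets did not pass the threshold: Alad was 0.11 (adjusted p = 0.834), Fech -0.02 (0.913) and the erythroid Alas2 -0.02 (0.918). Nt5c3, an erythrocyte nucleotidase that Pb inhibits, was 0.20 (0.787), the transferrin receptor gene Tfrc 0.18 (0.894), and the metallothionein genes Mt1 and Mt2 were 0.06 (0.862) and -0.09 (0.842). Alas2 at a level of 13.8 and Fech at 13.5 lay near the highest value on the arrays, 14.1, where differences can be compressed. Less bright probe sets of Fech gave 0.06, 0.12 and 0.09, each at an unadjusted p of 0.309 or more.

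**Figure D1:**
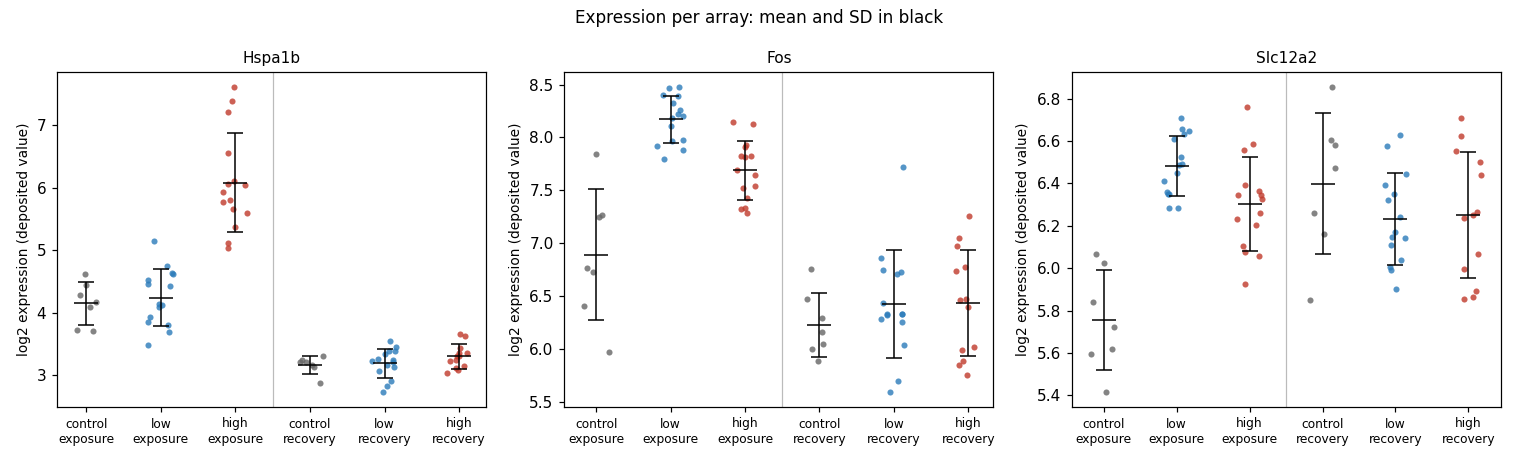
Deposited log2 expression of Hspa1b, Fos and Slc12a2 on each array (points) in the 6 groups by dose and collection, with group mean and SD in black. Hspa1b was 6.08 ± 0.79 in the high-dose exposure group and between 3.16 and 4.24 in the means of the control and low-dose groups, and Fos was highest, at 8.17, in the low-dose exposure group.

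After exposure to the low dose, 164 genes differed from control, 140 higher and 24 lower. Fos, an immediate early transcription factor, rose by 1.28 ± 0.18, from 6.89 ± 0.62 (SD, n = 7) to 8.17 ± 0.22 (SD, n = 15), with 14 of 15 arrays above every control (limma, adjusted p = 7.35e-06). Dusp1, a stress-induced phosphatase of MAP kinases, rose by 1.01 ± 0.16 (14 arrays, 3.48e-05), and Slc12a2 by 0.73 ± 0.11 to 6.48 ± 0.14 (SD, n = 15), with all 15 arrays above every control (9.02e-06). The other probe sets of Slc12a2 gave 0.20 and 0.25. The chemokine receptor gene Cxcr4 rose by 0.75 ± 0.16 (12 arrays, 0.00438) and Cybb, the catalytic subunit of the phagocyte NADPH oxidase, by 0.67 ± 0.11 (10 arrays, 0.000174). In contrast to the high dose, Hspa1b was 0.10 (0.914) and Dnajb1 0.18 (0.581), and the chaperone genes Hsph1 and Stip1 fell by 0.52 ± 0.12 (13 arrays, 0.0104) and 0.50 ± 0.10 (12 arrays, 0.00205).

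Other genes of large increase at the low dose were Trim7 (0.80, adjusted p = 0.00438), Ifi44l (0.75, 0.00438), the immunoglobulin gene Ighv14-2 (0.70, 0.018), the cold-inducible RNA-binding protein gene Cirbp (0.67, 0.0259) and Itih5 (0.67, 0.00185). Of the 15 low-dose arrays, 2, 12, 1, 3 and 13 lay above every control for these genes, in that order. Other probe sets of Trim7 gave 0.36 and 0.09, and that of Trpc1, which fell, gave -0.02. Genes that fell were Bmp2 (-0.60, 0.0104, 5 arrays below every control), Trpc1 (-0.50, 0.0259, 14 arrays), Triqk (-0.44, 0.0443, 12 arrays), Tfec (-0.40, 0.0307, 6 arrays), Tgfb1i1 (-0.38, 0.0465, 11 arrays), the platelet ATP receptor gene P2rx1 (-0.36, 0.0497, 11 arrays), Yap1 (-0.36, 0.041, 11 arrays) and Pde7b (-0.36, 0.045, 3 arrays). At least a 1.5-fold difference was reached by 24 genes. The share of higher calls was 232 of 314 after quantile normalization and 228 of 305 after cyclic loess. The count was 276, 74, 329, 35, 48 and 107 without control replicates 1, 2, 3, 5, 6 and 7, and 16 with cell marker means as covariates. It was 1406 with array weights, the highest over 20 alternatives.

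Monocyte, B cell and MHC class II genes were higher and platelet genes lower after the low dose. The monocyte call held, at adjusted p = 0.0382 with an estimated correlation, while the B cell, MHC class II and platelet calls each had adjusted p = 0.209 with an estimated correlation and 0.0372 by fry. Of 23 monocyte markers 7 rose over all genes and 17 adjusted over the list alone, among them the macrophage gene Mpeg1 (0.59), Adgre4 (0.57) and the growth factor receptor gene Csf1r (0.50). The monocyte list p was 3.51e-17. Of 24 B cell markers all were higher, 5 past the threshold and 17 adjusted over the list alone (list p = 2.74e-15). Examples were the B cell kinase gene Blk (0.60), the IgE receptor gene Fcer2a (0.62), Fcmr (0.56) and Bach2 (0.43). Of 18 MHC class II genes 6 rose and 10 did adjusted over the list alone, such as H2-Oa and H2-Ob (both 0.59), H2-Ea (0.54) and H2-Aa (0.47) (list p = 1.23e-10). All 26 platelet genes were lower, 0 past the threshold over all genes and 20 adjusted over the list alone (list p = 7.6e-18). Those of smallest p were Thbs1 (-0.52), F2rl2 (-0.36), Treml1 (-0.32) and Tubb1 (-0.32). In the controls after exposure the mean of the B cell genes, relative to all 72 arrays, was spread widely, -0.37 ± 0.63 (SD, n = 7), against -0.01 ± 0.20 (SD, n = 15) at the low dose. The platelet mean was 0.11 ± 0.17 (SD, n = 7) in controls and -0.15 ± 0.18 (SD, n = 15) at the low dose.

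Smaller shifts at the low dose were upward for 18 glucocorticoid response genes, of which 3 rose, Dusp1, Cxcr4 and Tsc22d3 (0.51), with 6 higher and 1 lower adjusted over the list alone (list p = 0.000722). Of 24 NF-kappaB targets Il18 (0.34) and Cd83 (0.44) rose, and 6 adjusted over the list alone (0.00238). Of 25 immediate early genes Fos and Dusp1 rose, with 2 higher and 1 lower adjusted over the list alone (0.0281). These 3 lists had adjusted p = 0.356, 0.404 and 0.556 with an estimated correlation. Of 26 heat shock and unfolded protein genes Hsph1 and Hyou1 (-0.24) fell, and 4 adjusted over the list alone (list p = 1.37e-05). Lower as lists were also 23 of 30 cell cycle genes (0.0281) and 9 of 11 facial tissue genes (0.0281), with 0 members past the threshold, over all genes or adjusted over the list alone. They had adjusted p = 0.306, 0.577 and 0.356 with an estimated correlation, in this order. The immediate early and facial calls were lost after quantile normalization (0.0616 and 0.0861) and cyclic loess (0.0783 and 0.111), the facial call also after centring (0.0583), and no called list turned direction. The other 18 lists did not pass, interferon and T cell genes at 0.0943 being nearest. Single members of such lists that changed were the iron regulator gene Hfe (0.59, adjusted p = 0.000495), Irf4 (0.52, 0.00185), Trat1 (-0.34, 0.0397) and Gata2 (-0.29, 0.0467). The iron, lead target, antioxidant, circadian, p53, oxidative phosphorylation and eosinophil lists had a median, mean and test that differed in sign. The genes named whatever their result did not pass: Alad was -0.10 (0.844), Alas2 -0.01 (0.981), Fech -0.01 (0.964), Nt5c3 0.13 (0.875), Tfrc -0.45 (0.581), Mt1 -0.06 (0.875) and Mt2 -0.0085 (0.989).

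After exposure Hspa1b was 1.84 ± 0.16 higher at the high than at the low dose, with 13 of 15 high-dose arrays above every low-dose array (limma, adjusted p = 1.85e-14), Hsph1 1.04 ± 0.10 (14 arrays, 1.99e-13) and Dnaja1 0.66 ± 0.08 (9 arrays, 9.51e-08). The carboxypeptidase gene Cpe (0.79 ± 0.22, 6 arrays, 0.00977) and Apol8 (0.70 ± 0.20, 4 arrays, 0.0109) were also higher. The B cell markers Fcer2a, an IgE receptor gene (-0.92 ± 0.12, 14 arrays, 6.01e-08), and Cd79b, a B cell receptor subunit gene (-0.82 ± 0.13, 14 arrays, 7.73e-06), were lower at the high dose. So were the MHC class II gene H2-DMb2 (-0.80 ± 0.12, 13 arrays, 9.69e-07) and the immunoglobulin gene Ighv14-2 (-0.94 ± 0.14, 13 arrays, 9.48e-07). Crisp3 was lower as well (-0.80 ± 0.13, 7 arrays, 1.62e-05).

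In all, 2349 genes differed between the doses after exposure, 760 higher and 1589 lower at the high dose, 60 of them by at least 1.5-fold. Against control the counts were 3 and 164, from 15 and 7 arrays rather than 15 and 15. The split depended on scaling: 1145 of 2603 were higher after quantile normalization, 1212 of 2354 after centring and 1167 of 2355 after cyclic loess. Array measures differed with the dose as well: the hybridisation controls averaged 10.5 at the high and 10.1 at the low dose (permutation test, two-sided, adjusted p = 0.0171), the interquartile range of relative log expression was 0.331 against 0.249 (0.00493), and the globin mean was 5.83 against 5.53 (0.0028). The 18S ribosomal RNA mean was 7.79 against 7.00 (0.0522, not past the threshold). With the hybridisation mean as a covariate 709 genes were called, with the 18S mean 893, and with cell marker means 88, where the high dose against control gave 195. Without the 4 arrays of wide relative log expression the count was 1445.

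By list, the B cell genes had the smallest p (list p = 1.78e-19, fry 5.11e-06). None of the 13 list calls between the doses held, with adjusted p = 0.212 to 0.734 with an estimated correlation, while by fry 10 of the 28 lists passed. All 24 were lower at the high dose, 22 past the threshold and 23 adjusted over the list alone, such as Cd22 (-0.80), Bank1 (-0.75) and Fcmr (-0.75). Of 18 MHC class II genes 13 fell, and 15 adjusted over the list alone (Cd74 -0.74, H2-Aa -0.72, H2-Ob -0.75, list p = 4.45e-13). Of 23 monocyte genes 14 fell and 1 rose, and 14 and 2 adjusted over the list alone (Ccr2 -0.70, Cybb -0.57, Ctss -0.41, Lyz2 -0.33, list p = 1.69e-06). The B cell and MHC class II lists had adjusted p = 0.212 with an estimated correlation, and the monocyte list 0.253. Of 26 platelet genes, all higher, 19 rose and 23 adjusted over the list alone (Thbs1 0.64, F2rl2 0.47, Itgb5 0.36, Gp6 0.36, list p = 1.03e-16). Of 33 erythroid genes 9 rose and 10 adjusted over the list alone (Aqp1 0.45, Gata1 0.41, Tal1 0.40, Gfi1b 0.33, list p = 1.31e-06). These lists had adjusted p = 0.227 and 0.404 with an estimated correlation. Of 26 heat shock genes 8 rose, with 8 higher and 2 lower adjusted over the list alone (Hsp90aa1 0.38, list p = 2.22e-06), and of 5 globin genes 2 rose and 4 adjusted over the list alone (Hbb-bh1 0.38, Hbb-y 0.35, 0.00384). Both had adjusted p = 0.227 with an estimated correlation. Of 30 cell cycle genes 10 rose and 11 adjusted over the list alone (Rrm2 0.64, Birc5 0.44, Top2a 0.36, Prc1 0.24, list p = 0.000277). Of 29 ribosomal protein genes 12 fell and 20 adjusted over the list alone (Rpl12 -0.34, 4.24e-05), and of 29 proteasome genes 6 fell and 12 adjusted over the list alone (Psmb7 -0.33, 0.00382). The last 3 lists had adjusted p = 0.273, 0.545 and 0.660 with an estimated correlation.

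Nearer the threshold was oxidative phosphorylation, with 5 of 38 genes lower and 1 adjusted over the list alone (Uqcrc1 -0.28, list p = 0.0459). Of 13 heme synthesis genes Abcb6 (0.30), Slc25a38 (0.21) and Cpox (0.20) rose and Alas1 (-0.14) fell, as many as adjusted over the list alone (0.0459). Of 11 facial tissue genes 0 passed either way (0.0364). These lists had adjusted p = 0.734, 0.545 and 0.404 with an estimated correlation. The facial call was lost under each rescaling (0.120 after quantile normalization), the heme call after quantile normalization (0.0587) and the oxidative phosphorylation call after centring (0.0678) and cyclic loess (0.265). No called list turned direction. Lists that did not pass held single changed genes. Of the NF-kappaB targets 8 fell and 2 rose (Cd40 -0.57, Cd83 -0.39, Nfkbia -0.34, list p = 0.0929), and of the immediate early genes 8 fell and 1 rose (Fos -0.48, Ier2 -0.23, 0.355), as many as adjusted over the list alone. Of the plasma cell genes 3 fell (Pou2af1 -0.65, Mzb1 -0.57, Irf4 -0.47, 0.355), with a median of 0.03 and a mean of -0.13 over the list, and of the neutrophil genes 4 fell and 1 rose (S100a8 -0.29, Il1r2 0.53, 0.231). Tfrc was 0.62 higher (adjusted p = 0.0486) within an iron list that was not shifted (0.861), and Slc39a4 0.30, Mtf1 0.17 and Slc30a5 -0.26 changed within the metal transport list (0.355). The other lists lay between 0.231 and 0.956, and of them the interferon, circadian and p53 lists had a test opposite in sign to their median and mean.

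**Figure D2:**
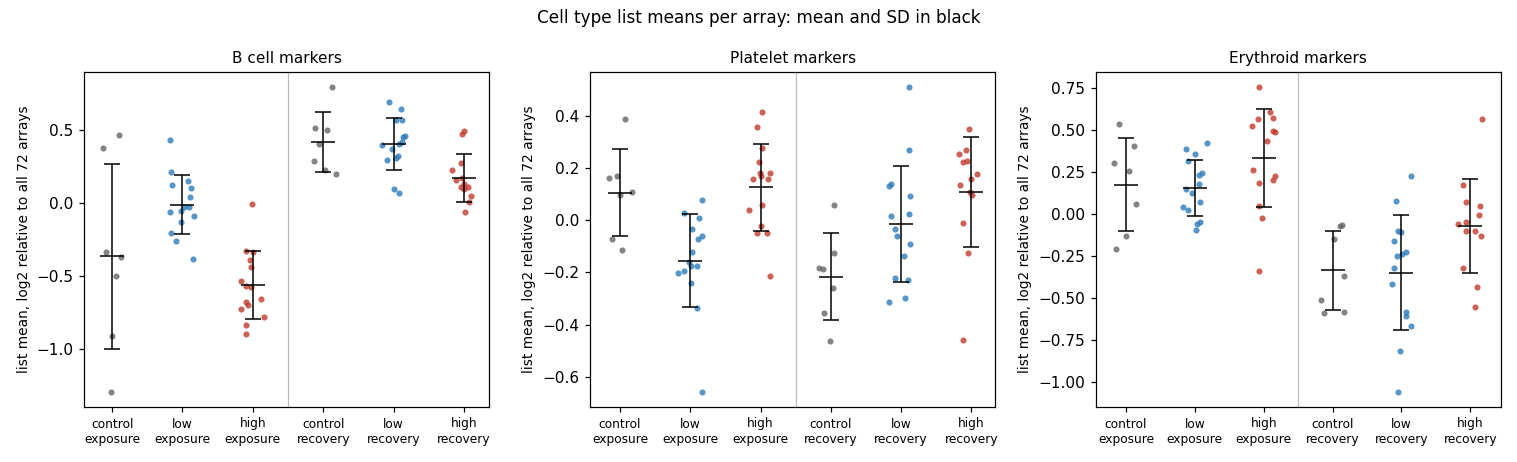
Mean log2 level of the B cell, platelet and erythroid marker lists on each array, relative to the mean over all 72 arrays (points), with group mean and SD in black. The B cell mean was -0.37 ± 0.63, -0.01 ± 0.20 and -0.56 ± 0.23 (SD, for control, low and high dose) after exposure and 0.42 ± 0.21, 0.40 ± 0.18 and 0.17 ± 0.16 after recovery.

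The calls of both doses after exposure shared 1 higher gene, Slc12a2, and 0 lower genes. Unchanged groups simulated against the same controls shared a median of 0 higher genes (mean 0.96, highest 96), and independent lists of these sizes would share 0.0334. With separate controls for each dose the median shared was 0. Across genes, which are not independent replicates, the log2 differences correlated at 0.188, below the simulated median of 0.686, and the covariance was 0.00285 against a simulated 0.00670, a difference of -0.00386. After splitting the controls the correlation was -0.06.

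After recovery, 54 genes differed between the high dose and control, 51 higher and 3 lower, and platelet and erythroid genes were among those that rose. The platelet collagen receptor gene Gp6 rose by 0.50 ± 0.10, with 12 of 13 arrays above every control (limma, adjusted p = 0.00715), and Gp5, a subunit of the von Willebrand factor receptor, rose by 0.50 ± 0.10 (12 arrays, 0.016). The level of Gp5 went from 9.02 ± 0.19 (SD, n = 7) to 9.52 ± 0.25 (SD, n = 13). The serotonin transporter gene Slc6a4 (0.50, 11 arrays, 0.0349), the water channel gene Aqp1 (0.50, 13 arrays, 0.0398), and Mfsd2b, a sphingosine-1-phosphate exporter of red cells and platelets (0.51, 9 arrays, 0.0286), rose as well. So did Slc22a23 (0.50, 11 arrays, 0.00715), Wnk4 (0.50, 8 arrays, 0.0258), Pcyt1b (0.50, 9 arrays, 0.0349), Clca3a1 (0.54, 8 arrays, 0.0439) and Trim37 (0.55, 11 arrays, 0.0373). The 3 genes that fell were Cox16, an assembly factor of cytochrome oxidase (-0.57 ± 0.10, 8 arrays below every control, 0.00316), Srsf6 (-0.25, 8 arrays, 0.0439) and Arnt (-0.25, 11 arrays, 0.0429). Other probe sets of Clca3a1 and Pcyt1b gave 0.15 and 0.13, those of Trim37 gave 0.28, 0.14, -0.01 and -0.03, and those of Arnt lay between -0.0046 and 0.05.

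At an unadjusted p under 0.05 there were 1377 genes for the high dose after recovery, and 0 of the called genes reached 1.5-fold. The count was 109, 26, 2, 4, 21 and 7 without control replicates 1, 2, 3, 5, 6 and 7, 1 with cell marker means as covariates, 6 with the 3' to 5' covariates and 10 with the hybridisation covariate. Over 20 alternatives it ran from 0, with a 1.5-fold minimum, to 427 with array weights. Of the 26 platelet genes all were higher, 5 past the threshold and 25 adjusted over the list alone, Treml1 (0.46, adjusted p = 0.0349) and Gp9 (0.45, 0.0473) among them. The platelet list p was 5.95e-29, with adjusted p = 0.121 with an estimated correlation and 0.0185 by fry. The platelet mean was -0.22 ± 0.17 (SD, n = 7) in controls and 0.11 ± 0.21 (SD, n = 13) at the high dose. After exposure it was 0.11 ± 0.17 (SD, n = 7) in controls and 0.13 ± 0.17 (SD, n = 15) at the high dose. Of 33 erythroid genes 32 were higher, 3 past the threshold and 7 adjusted over the list alone, among them the erythroid factor genes Gata1 (0.46, adjusted p = 0.00316) and Nfe2 (0.36). The erythroid list p was 6.15e-13, with adjusted p = 0.415 with an estimated correlation. Higher as lists were 26 of 36 interferon genes (2 adjusted over the list alone, list p = 0.000958), 22 of 30 cell cycle genes (0.00107) and 11 of 13 heme synthesis genes (0.013). Lower as lists were 23 of 24 B cell genes (6.98e-07), 27 of 29 ribosomal genes (7.27e-05), 23 of 24 NF-kappaB targets (0.00132), 16 of 18 MHC class II genes (0.0101), 20 of 25 immediate early genes (2 adjusted over the list alone, 0.0129) and 9 of 10 eosinophil genes (0.0402). Where no count is given, 0 members passed adjusted over the list alone. These lists had adjusted p = 0.585 with an estimated correlation, except ribosomal 0.586 and MHC class II 0.613, and each kept its direction after rescaling. Of the Pb target genes none passed, Fech (-0.02) included. Tfrc was 0.92 ± 0.30 (adjusted p = 0.165), Alad 0.28 (0.430), Nt5c3 0.27 (0.601), Mt1 0.24 (0.227), Mt2 0.05 (0.880) and Alas2 0.02 (0.869).

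After recovery from the low dose, no gene passed the threshold against control. Nearest was Cox16 (-0.46 ± 0.10, limma, adjusted p = 0.342), which was also the called gene farthest below control at the high dose after recovery. It was followed by the erythroid factor gene Gata1 (0.31), the red cell membrane gene Stom (0.28), Dapk1 (0.29) and Hexim2 (0.33), each at an adjusted p of 1. By limma 0 of 12589 genes passed and 295 had an unadjusted p under 0.05, fewer than the 629 of chance. All 26 platelet genes were higher, 0 past the threshold and 0 adjusted over the list alone (list p = 7.86e-28, fry 0.559, adjusted p = 0.143 with an estimated correlation). Lower were 13 of 15 circadian genes (0.0217, adjusted p = 0.161 with an estimated correlation) and 16 of 18 NK and cytotoxic genes (0.0217, adjusted p = 0.915 with an estimated correlation). The number of shifted lists, 3, became 7 after quantile normalization and 6 after cyclic loess, these 3 included. Alad (-0.06), Alas2 (0.01), Fech (-0.03), Nt5c3 (-0.08), Tfrc (0.25), Mt1 (0.05) and Mt2 (0.15) each had an adjusted p of 1.

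Between the doses after recovery, erythroid genes were higher and B cell genes lower at the high dose, with no single gene past the threshold. None of the 12 list calls held, with adjusted p = 0.242 to 0.702 with an estimated correlation, and by fry 0 lists passed, the smallest adjusted p being 0.0876. By limma 0 genes passed and 1765 had an unadjusted p under 0.05. Odf3 (0.37), Scrn2 (0.36), Ncapg (0.36), Disp3 (0.27) and Arnt (-0.22) came nearest, each at an adjusted p of 0.125. Array weights raised the count to 95. Of 33 erythroid genes 32 were higher, 10 of them past the threshold adjusted over the list alone (Ermap 0.55, Aqp1 0.38, list p = 1.01e-16). All 26 platelet genes were higher (3.03e-07). These lists had adjusted p = 0.242 and 0.587 with an estimated correlation. Also higher were 23 of 30 cell cycle genes (4 adjusted over the list alone, 1.14e-05), 11 of 13 heme synthesis genes (3 adjusted over the list alone, 0.000482), 5 of 5 globin genes (1 adjusted over the list alone, 0.00078) and 24 of 36 interferon genes (0.0124). They had adjusted p = 0.258, 0.336, 0.242 and 0.702 with an estimated correlation. Lower were 23 of 24 B cell (3.62e-08), 17 of 18 MHC class II (0.000482), 22 of 24 NF-kappaB (0.00078), 27 of 29 ribosomal (0.00142), 20 of 23 monocyte (0.0124) and 9 of 10 eosinophil genes (0.0407). They had adjusted p = 0.517, 0.623, 0.517, 0.702, 0.684 and 0.663 with an estimated correlation. The globin mean was 5.43 against 5.19 (permutation test, two-sided, adjusted p = 0.0463).

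Both doses shared 0 called genes after recovery. The log2 differences correlated at 0.536 across genes, against a simulated median of 0.676, with a covariance of 0.00542 against 0.00668 and a difference of -0.00127. With split controls the correlation was -0.03.

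Between the collections, blood of control mice itself changed in 4544 genes, 2834 higher and 1710 lower after recovery. Trim7 rose by 1.72 ± 0.20 with all 7 arrays above every exposure array (limma, adjusted p = 7.61e-10). Srpk3 (1.51 ± 0.19, 7 arrays, 5.08e-09), Taf15 (1.36 ± 0.17, 7 arrays, 6.56e-09), the B cell factor gene Ebf1 (1.29 ± 0.23, 3 arrays, 7.86e-06) and Crisp3 (1.28 ± 0.20, 5 arrays, 6.92e-07) rose. The platelet ADP receptor gene P2ry12 fell by 1.88 ± 0.23 (7 arrays, 3.57e-09), Tfrc by 1.48 ± 0.34 (5 arrays, 0.000404) and the platelet thrombospondin gene Thbs1 by 1.35 ± 0.18 (7 arrays, 2.29e-08). Snap23 (-1.28 ± 0.19, 7 arrays, 3.76e-07) and the red cell membrane gene Epb42 (-1.25 ± 0.33, 5 arrays, 0.00223) fell too. A further probe set of Ebf1 moved the other way (-0.39), that of Taf15 gave -0.06, and those of Tfrc lay between -0.38 and -0.17. Of 24 B cell genes 23 rose, with 23 higher and 1 lower adjusted over the list alone (Cd22 1.22, Fcmr 1.21, Fcer2a 1.20, Blk 1.07, list p = 1.09e-11). Of 18 MHC class II genes 14 rose and 1 fell, and 16 and 1 adjusted over the list alone (H2-Oa 1.21, 4.14e-08). Of 23 monocyte genes 16 rose and 1 fell, and 17 and 1 adjusted over the list alone (Cybb 1.24, Csf1r 1.07, 2.97e-06). Each of these had adjusted p = 0.535 with an estimated correlation. Of 33 erythroid genes 21 fell and 1 rose, and 25 and 1 adjusted over the list alone (Gata1 -0.59, Epor -0.55, list p = 7.55e-08). Of 26 heat shock genes 10 fell and 1 rose (Hspa1b -0.98, Hsph1 -0.64, 0.00319), and of 30 cell cycle genes 7 fell and 3 rose (Rrm2 -1.24, 0.00741), as many as adjusted over the list alone. Each of these had adjusted p = 0.601 with an estimated correlation. Of 26 platelet genes 13 fell and 2 rose, and 14 and 2 adjusted over the list alone (4.95e-05). Of 29 ribosomal genes 15 rose and 16 adjusted over the list alone (0.00124), and of 29 proteasome genes 11 rose, as adjusted over the list alone (0.0409). These had adjusted p = 0.634, 0.644 and 0.758 with an estimated correlation, and the proteasome call was lost after cyclic loess (0.146).

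At the low dose 5552 genes changed between the collections, 3301 higher and 2251 lower after recovery. Fos fell by 1.75 ± 0.14, with 15 of 15 arrays below every exposure array (limma, adjusted p = 2.78e-15). Epb42 (-1.69 ± 0.23, 13 arrays, 1e-08), Yipf4 (-1.39 ± 0.16, 15 arrays, 8.92e-11), the erythroid gene Trim10 (-1.32 ± 0.21, 13 arrays, 5.3e-07) and Diaph3 (-1.27 ± 0.16, 12 arrays, 9.09e-10) fell. Taf15 (1.07 ± 0.12), the von Willebrand factor gene Vwf (1.02 ± 0.10), Foxp1 (1.01 ± 0.10), Trim7 (0.93 ± 0.14) and Papola (0.92 ± 0.11) rose. Of 15 arrays 13, 15, 15, 10 and 13 lay above every exposure array for these, with adjusted p-values between 2.9e-12 and 5.66e-08. Other probe sets of Yipf4 (0.25), Taf15 (-0.15) and Papola (-0.22) moved the other way at an unadjusted p under 0.05. Of 33 erythroid genes 25 fell and 26 adjusted over the list alone (Car2 -1.14, Car1 -0.79, list p = 1.63e-08). Of 25 immediate early genes 11 fell, as adjusted over the list alone (Dusp1 -1.26, Klf6 -0.56, 0.000128), and of 18 iron genes 7 fell and 2 rose, and 8 and 2 adjusted over the list alone (0.0238). Each had adjusted p = 0.679 with an estimated correlation. Of 24 B cell genes 19 rose and 1 fell, and 20 and 1 adjusted over the list alone (Cd22 0.75, Pax5 0.75, list p = 2.26e-05). Further shifts had the same counts adjusted over the list alone: 14 of 18 MHC class II (0.000157), 17 of 29 ribosomal (0.00175) and 15 of 29 proteasome genes rose, of the last 3 fell (0.0347). So had 26 platelet genes, of which 9 rose and 3 fell (Itgb3 0.72, Itga2b 0.60, P2ry12 -1.05, 0.0238), and 30 cell cycle genes, of which 11 fell and 6 rose (0.0289). Each of these, with the B cell list, had adjusted p = 0.812 with an estimated correlation. Of 5 globin genes 3 fell and 4 adjusted over the list alone (0.0347, adjusted p = 0.726 with an estimated correlation). The cell cycle and globin calls were lost under each rescaling (0.0629 and 0.120 after quantile normalization), the platelet call after centring (0.0529) and cyclic loess (0.0776), and the proteasome call after cyclic loess (0.112).

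At the high dose 6189 genes changed, 3695 higher and 2494 lower after recovery. Hspa1b fell by 2.78 ± 0.16 to 3.30 ± 0.19 (SD, n = 13), with 13 of 13 arrays below every exposure array (limma, adjusted p = 2.33e-23). Its level after recovery was 3.16 ± 0.14 (SD, n = 7) in controls and 3.20 ± 0.23 (SD, n = 15) at the low dose. P2ry12 (-1.33 ± 0.16), the myo-inositol transporter gene Slc5a3 (-1.27 ± 0.10) and Fos (-1.26 ± 0.15) fell with all 13 arrays below, and Epb42 (-1.27 ± 0.24) with 3 arrays below, at adjusted p-values between 2.92e-17 and 7.87e-06. Trim7 (1.32 ± 0.14), Fcer2a (1.29 ± 0.12), Srpk3 (1.28 ± 0.13), Cd22 (1.21 ± 0.11) and Ighv14-2 (1.17 ± 0.14) rose, each with all 13 arrays above every exposure array (3.1e-10 or smaller). Other probe sets gave 0.63 and 0.10 for Trim7 and -0.21 and -0.03 for Slc5a3. Of 26 heat shock genes 13 fell and 2 rose (Dnaja1 -1.04, Hsph1 -0.95, Hsp90aa1 -0.56, list p = 6.17e-05), and of 25 immediate early genes 12 fell (Dusp1 -0.94, Klf6 -0.68, 0.000107). They had adjusted p = 0.508 and 0.501 with an estimated correlation. Of 24 B cell genes 23 rose and 1 fell (1.32e-11), and of 18 MHC class II genes 15 rose (H2-DMb2 1.14, Cd74 0.97, 1.76e-09), both with adjusted p = 0.501 with an estimated correlation. Of 29 ribosomal genes 21 rose (6.17e-05), of 29 proteasome genes 18 rose and 1 fell (0.000931), and of 23 monocyte genes 14 rose and 1 fell (0.00118). Of 33 erythroid genes 21 fell (1.49e-06), of 30 cell cycle genes 15 fell and 6 rose (0.0168), and of 18 glucocorticoid genes 8 fell and 2 rose (0.0204). Each of these 6 lists had adjusted p = 0.592 with an estimated correlation. Adjusted over the list alone the counts were 22 ribosomal, 22 erythroid and 16 lower cell cycle genes, and for the other lists as over all genes. Of 5 globin genes 3 fell (0.0237, adjusted p = 0.508 with an estimated correlation), a call lost under each rescaling (0.0929 after quantile normalization). Platelet genes were not shifted, with 7 of 26 higher and 4 lower (0.884, median 0.00, mean -0.02).

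Between the collections 723, 345 and 468 genes differed by at least 1.5-fold in control, low-dose and high-dose mice. The higher calls were 2499 of 4985, 2433 of 5030 and 2417 of 4911 in controls after quantile normalization, centring and cyclic loess. They were 2907 of 5864 and 2782 of 5827 at the low dose after centring and cyclic loess, and 3209 of 6686, 3104 of 6994 and 2989 of 6568 at the high dose. Called lists kept their direction under each rescaling, and by fry 12, 13 and 16 of the 28 lists passed in controls and at the low and high dose. Signs of RNA integrity moved with the collection: the Gapdh 3' minus 5' difference was 0.909 after recovery and 0.542 after exposure in controls (exact permutation test, two-sided, p = 0.00117, adjusted p = 0.00453). It was 0.925 and 0.534 at the low dose (permutation test, two-sided, p = 1e-05, the smallest it can give, adjusted p = 0.000175) and 0.845 and 0.564 at the high dose (p = 0.00015, adjusted p = 0.00131). The beta-actin difference was 0.31, 0.22 and 0.16 higher after recovery (adjusted p = 0.00291, 0.000175 and 0.00493 by the same tests), and the globin mean changed by -0.32, -0.34 and -0.39 (adjusted p = 0.0291, 0.00315 and 0.00147). The 18S ribosomal RNA mean changed by -0.68 at the low dose and -1.36 at the high dose (permutation tests, adjusted p = 0.0173 and 0.000933) and was -0.62 in controls (exact permutation test, adjusted p = 0.174). The poly-A controls changed by -1.07 at the high dose and the range of relative log expression by 0.0754 at the low dose (permutation tests, adjusted p = 0.0377 each). With cell marker means as covariates 1578 genes were called in controls.

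**Figure D3:**
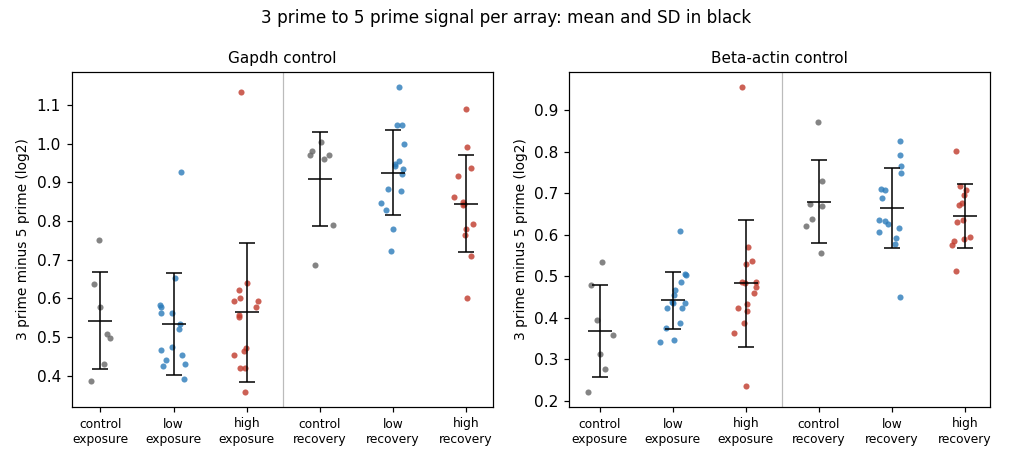
The 3' minus 5' difference (log2) of the Gapdh and beta-actin control probe sets on each array (points) in the 6 groups, with group mean and SD in black. The Gapdh means lay between 0.534 and 0.564 after exposure and between 0.845 and 0.925 after recovery.

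The effect of the high dose differed between recovery and exposure for Hspa1b (-1.80 ± 0.28, limma, adjusted p = 0.000176), the single gene past the threshold, with 432 genes at an unadjusted p under 0.05. Slc12a2 (-0.70, 0.105), Thbd (-0.62, 0.148), Tubb6 (-0.52, 0.433) and Klf10 (-0.52, 0.594) were not past it. The effect of the low dose differed for 3 genes: Slc12a2 (-0.90 ± 0.15, 0.000829), the death-associated kinase gene Dapk1 (0.60 ± 0.12, 0.0149) and the cell cycle inhibitor gene Cdkn2b (0.60 ± 0.12, 0.0217), with 1064 at an unadjusted p under 0.05. Slc12a2 in controls was 5.75 ± 0.24 after exposure and 6.40 ± 0.33 after recovery (SD, n = 7 each), against 6.48 ± 0.14 and 6.23 ± 0.22 at the low dose (SD, n = 15 each). Its other probe sets gave -0.13 and -0.35 in the interaction. Trpc1 (0.81, 0.0513), Hfe (-0.68, 0.0513), Fos (-1.09, 0.0576) and Dusp1 (-0.76, 0.0981) were not past the threshold. The low-dose count was 33, 1, 52, 36 and 5 without exposure control replicates 1, 2, 3, 4 and 7, and 133, 5, 1, 26 and 1 without recovery control replicates 1, 2, 3, 4 and 5. The high-dose count was 2 without exposure control replicate 4 and without recovery control replicate 1 or 5. After quantile normalization 44 of 78 low-dose calls were higher, after cyclic loess 23 of 45, and with cell marker means as covariates the count was 0. With the 18S covariate the counts were 3 at the high and 14 at the low dose, and with the 3' to 5' covariates 19 at the low dose.

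Platelet genes had the smallest p of the 28 lists in the interaction of the low dose and in that of the high dose. Both rest on the same 14 control arrays, whose platelet mean went from 0.11 to -0.22 between the collections, against -0.15 to -0.01 at the low and 0.13 to 0.11 at the high dose. Relative to these controls all 26 genes lay higher after recovery. By fry 2 lists passed at the low and 0 at the high dose. At the low dose 26 were past the threshold adjusted over the list alone and 0 over all genes (Alox12 0.57, Treml1 0.57, Gp5 0.55, Gp6 0.54). This call (list p = 1.23e-35) held, at adjusted p = 0.0459 with an estimated correlation and 0.0115 by fry. At the high dose 6 passed adjusted over the list alone and 0 over all genes (Gp9 0.51, Gp6 0.42, Treml1 0.41, Gp1bb 0.40, list p = 3.27e-23, adjusted p = 0.144 with an estimated correlation). Lower at the low dose were 21 of 23 monocyte genes (9 lower and 1 higher adjusted over the list alone, 6.19e-11), 24 of 24 B cell genes (1 adjusted over the list alone, 5.2e-11) and 17 of 18 MHC class II genes (6 adjusted over the list alone, 1.08e-06). They had adjusted p = 0.150, 0.328 and 0.35 with an estimated correlation. Of 26 heat shock genes 19 were higher (1 adjusted over the list alone, Hsph1 0.58, 5.21e-05, adjusted p = 0.328 with an estimated correlation). NF-kappaB (0.00724), immediate early (0.00846), NK (0.0171), glucocorticoid (0.0181) and circadian genes (0.0319) lay lower, with adjusted p = 0.505, 0.44, 0.796, 0.571 and 0.321 with an estimated correlation. At the high dose 17 of 18 glucocorticoid (2.28e-05), 20 of 24 NF-kappaB (3.21e-05), 17 of 23 monocyte (3.21e-05) and 16 of 25 immediate early genes (9.52e-05) were lower. So were 9 of 10 eosinophil (0.000272), 12 of 15 circadian (0.000717) and 17 of 18 NK genes (0.000786). These 7 lists had adjusted p = 0.222, 0.222, 0.337, 0.222, 0.222, 0.0592 and 0.74 with an estimated correlation. Heat shock genes lay lower (15 of 26, 0.0391), with a median that was above 0 after quantile normalization, and T cell (21 of 26, 0.0271) and erythroid genes (26 of 33, 0.0152) higher. Each had adjusted p = 0.819 with an estimated correlation, and the erythroid call was lost after quantile normalization (0.0617) and cyclic loess (0.109).

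Against control, 0 of 24 tests of array quality passed after adjustment. The smallest was the interquartile range of relative log expression at the low dose after exposure, 0.249 against 0.316 in controls (exact permutation test, two-sided, p = 0.00255, adjusted p = 0.0612). At the high dose after exposure the poly-A controls were 9.87 against 8.70 (exact permutation test, two-sided, p = 0.0322, adjusted p = 0.332) and the hybridisation controls 10.5 against 10.1 (p = 0.0457, adjusted p = 0.332, by the same test). The 18S ribosomal RNA mean was 7.79 against 7.00 there (p = 0.0746, adjusted p = 0.298 over 4 further tests of 18S, by the same test), and the other 3 had an adjusted p of 0.999.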

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

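The tests of blood cell mix and RNA quality for the difference between doses, of RNA quality and batch for the difference between collections, and of RNA quality for the heat shock and immediate early genes were chosen only after the result was seen, as was the rule that a correction argues against RNA quality only where it moves the median gene by at least 0.5 SE.

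The effect of high Pb on Hspa1b differed between recovery and exposure (interaction -1.80), as did the effect of low Pb on Slc12a2 (-0.90), Dapk1 (0.60) and Cdkn2b (0.60). Of 142 series of values of the 7-array control groups, 4 held an array far from the rest, where chance alone would mark about 1 in 20. The gap of the farthest array, as a share of the group's range, was 0.659 for the eosinophil and basophil mean after exposure (replicate 7 at 5.65, the nearest at 5.17), 0.612 for Alas2 after recovery (replicate 5 at 13.7, the nearest at 13.8), 0.653 for Fech after recovery (replicate 5 at 13.5, the nearest at 13.6) and 0.583 for the facial tissue mean after recovery (replicate 4 at 4.83). The poly-A spike-in probe sets, which enter no comparison of genes, averaged 8.70 in exposure controls and far more on 6 arrays of treated mice: 13.0 and 13.1 on low-dose exposure replicates 8 and 12, 13.0, 13.1 and 13.0 on high-dose exposure replicates 9, 10 and 12, and 13.2 on low-dose recovery replicate 8.

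High- and low-dose arrays differed in 2349 genes after exposure. A different mix of blood cells stays open: with marker means of 6 cell types as covariates, 28.6% of the median absolute log2 difference of 2274 genes outside the marker lists was left, 0.0697 against 0.244, and because the markers themselves differed with the dose, this could as well be an effect of Pb on cell numbers, not tested further. RNA quality stays open too: 88.1% of the genes stayed past the threshold with the 3' to 5' covariates, but these moved the median gene by only 0.114 SE and so decide nothing. With the mean of 18S ribosomal RNA as a covariate 36.3% stayed past the threshold, with 82.2% of the median absolute difference left and a median SE of 0.0756. The hybridisation level may also contribute, as 30.1% of the genes stayed past the threshold with it as a covariate, though 83.5% of the median absolute difference was left and the median SE grew from 0.0732 to 0.0780.

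Recovery and exposure arrays differed in 3339 genes in the same direction at every dose, controls included, so Pb is not needed for this pattern. As measured by the 3' to 5' covariates, RNA quality is argued against as the whole cause. With them 71.9% of these genes stayed past the threshold at all 3 doses. The median gene moved by 0.788 SE in controls, 1.23 at the low and 0.846 at the high dose. Cell mix may be part of the cause but not all, as marker covariates left 55.1% of the median absolute difference (0.200 against 0.363, 3282 genes). What these covariates miss stays open, and ribosomal RNA was not tested here. A processing batch and the collection cannot be told apart, because the labels give no batch and 66 of 72 arrays lay on their own collection's side of 0.720 in the Gapdh 3' to 5' difference. Age of the mice differs between the collections, as does repeated bleeding in the exposed mice (for controls the labels do not say), and both stay open, untested.

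Hspa1b and Dnajb1 at the high dose and Fos and Dusp1 at the low dose, genes that respond quickly to stress of cells, rose after exposure. Cell mix is argued against: the share of the log2 difference left with marker covariates, averaged over the 4 genes, was 102%, and the mean difference was 1.21 before and after. RNA quality stays open: 3 of the 4 stayed past the threshold with the 3' to 5' covariates (Hspa1b 1.69, Fos 1.31, Dusp1 0.98), but these moved the median gene by only 0.267 SE in the high-dose and 0.205 SE in the low-dose comparison. The call of Dnajb1 ended by a smaller difference at an equal SE, from 0.64 ± 0.12 to 0.54 ± 0.12 (adjusted p = 0.0921). The Pb dose is a candidate explanation, as are differences in handling of blood between groups, which no label records and which were not tested.

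Whether chance can be excluded was tested with 100 splits of the compared arrays into groups of the same sizes, the real split included. Chance was excluded where only the real split reached the gene count. These were low dose against control (real 164, highest other 25) and high against low dose after exposure (2349, 4). So were high dose against control after recovery (54, 1) and recovery against exposure at the low (5552, 1763) and high dose (6189, 3550). Chance was not firmly excluded where 2 to 4 splits did, as the tests were not corrected for their number. These were recovery against exposure in controls (2 splits, 4544, 5500), the low-dose interaction (4, 3, 1816) and the lists of high dose against control after exposure (3, 15, 17). Chance was not excluded for the count of 3 genes of high dose against control after exposure (9 splits, highest other 1656), the count of 1 gene of the high-dose interaction (5 splits, highest other 1891), and the genes at an unadjusted p under 0.05 of low dose against control (68 splits, real 295, highest other 4826) and of high against low dose after recovery (12 splits, real 1765, highest other 3785). These counts say nothing of single genes, and Hspa1b had an adjusted p of 5.56e-11 by limma at the high dose after exposure and 0.000176 in the interaction. Why single splits gave counts far above the real ones was not tested.

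For the other list counts chance was not excluded. As many lists were called by 31 splits for low dose against control after exposure (real 10, highest other 15), 6 for high against low dose after exposure (13 and 16), 16 for high dose against control after recovery (11 and 17), 94 for low dose against control after recovery (3 and 14) and 17 for high against low dose after recovery (12 and 18). Between the collections the numbers were 44 in controls (9 and 14), 25 at the low dose (10 and 15) and 26 at the high dose (11 and 16), and for the interactions 22 at the high dose (11 and 14) and 37 at the low dose (10 and 15). The other splits called a median of 7 or 8 lists, so the preset correlation of camera calls lists in these arrays whatever the grouping.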

How the results depend on the processing

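Leaving out the 6 arrays with high poly-A controls (genes and lists), array weights set per group, the 3' to 5', hybridisation and 18S ribosomal RNA covariates, leaving out each control array, and the lists after quantile normalization and cyclic loess were added after the data were examined.

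No named gene that was called changed sign under any alternative. Of 80 such calls, 41 were kept with cell markers as covariates, 66 with the 3' to 5' covariates, 70 with the hybridisation covariate, 71 with no filter, 73 with each probe set tested by itself, 75 with the mean of probe sets, 78 with array weights per group, all of the 75 measured with a stricter filter, all of the 79 measured without probe sets of possible cross-hybridisation, and 79 or all under the other alternatives except the replicate numbers below. Over 20 alternatives the gene count ran from 1 to 195 for high dose against control after exposure (within 1.5 times the main count in 7), 16 to 1406 for low dose (13) and 60 to 3139 for high against low dose (15). After recovery it ran from 0 to 427 (9), 0 to 1 (17) and 0 to 95 (18) in the same order. Between the collections it ran from 723 to 6758 in controls (18), 345 to 6788 at the low dose (19) and 468 to 7423 at the high dose (19), and for the interactions from 1 to 15 at the high dose (12) and 0 to 716 at the low dose (9). The contrast between doses after exposure and those between collections held the highest counts, except with cell markers as covariates. Low signals over background limit what can be seen in dim genes. The cause of the differences below was not tested, except that a fold minimum lowers a count by construction.

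Counts that moved by over 1.5 times were as follows, with HE, LE and HL for high dose against control, low dose against control and high against low dose after exposure, HR, LR and HLR for the same after recovery, and IH and IL for the interactions of the high and the low dose. Genes with a stricter filter were 9 (HE) and 15 (IL), with no filter 24 (HR), with the mean of probe sets 11 (HE) and 9 (IL). After quantile normalization they were 75 (HE), 314 (LE), 96 (HR), 2 (IH) and 78 (IL), after centring 36 (HE), 282 (LE), 140 (HR), 2 (IH) and 66 (IL), and after cyclic loess 68 (HE), 305 (LE), 123 (HR), 1 (LR), 2 (IH) and 45 (IL). Array weights gave 13 (HE), 1406 (LE), 427 (HR), 95 (HLR), 6 (IH) and 716 (IL). Without the arrays that stood apart in relative log expression the counts were 13 (HE), 1445 (HL), 1 (LR) and 2 (IH), and without those with high poly-A controls 5 (HE), 308 (LE) and 110 (IL). Trended and robust moderation gave 5 (HE). Fits of only the groups compared gave 15 (HR) and 1 (HLR). With cell markers as covariates the counts were 195 (HE), 16 (LE), 88 (HL), 1 (HR), 1 (LR), 1578 (collections in controls), 15 (IH) and 0 (IL). The 3' to 5' covariates gave 1 (HE), 6 (HR) and 19 (IL), the hybridisation covariate 6 (HE), 709 (HL), 10 (HR) and 3 (IH), and the 18S covariate 15 (HE), 893 (HL), 3 (IH) and 14 (IL). A fold change of at least 1.5 left 24 (LE), 60 (HL), 0 (HR), and 723, 345 and 468 between the collections in controls, low and high dose. With the controls split between the doses 0 higher genes were shared after exposure. Leaving out each control array gave 3 to 26 (HE), 35 to 329 (LE), 2 to 109 (HR), 0 to 1 (LR), 3791 to 5149 (collections in controls), 1 to 2 (IH) and 1 to 133 (IL).

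Numbers of called lists with an estimated correlation were 0, except 1 for LE and 1 for IL. By fry they were 0 (HE), 4 (LE), 10 (HL), 1 (HR), 0 (LR), 0 (HLR), 12, 13 and 16 between the collections in controls, low and high dose, 0 (IH) and 2 (IL). With cell markers as covariates they were 3 (HE), 6 (LE), 3 (HL), 5 (HR), 0 (LR), 6 (HLR), 2, 2 and 5 between the collections in controls, low and high dose, and 4 (IL). For LR 10 lists were called without the arrays that stood apart, 5 with no filter, 7 after quantile normalization and 6 after cyclic loess, and at the low dose between the collections 6 without the arrays that stood apart.

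Log2 differences with an opposite sign, none of them past the threshold under any of these settings, were as follows. With the 3' to 5' covariates Alad (HE) was -0.056, Tfrc (HE) -0.064 and Alas2 (LE) 0.00066. After centring Alas2 (HE) was 0.017, Fech (HE) 0.016 and Fech (HR) 0.016. After cyclic loess Alas2 was 0.026 (HE), 0.011 (LE), -0.015 (HR) and -0.036 (LR), Fech 0.025 (HE) and 0.0047 (LE), and Mt2 (LE) 0.011. Without the high poly-A arrays Alas2 was 0.010 (HE) and 0.011 (LE), and Fech 0.0035 (HE) and 0.0068 (LE). With the mean of probe sets Fech was 0.061 (HE), 0.011 (LE) and 0.060 (HR), Mt1 (LE) 0.084 and Alad (LR) 0.041. With cell markers Nt5c3 was -0.044 (HE), -0.018 (HR) and 0.0048 (LR), Mt1 (HE) -0.036, Alas2 (LE) 0.0033, and Mt2 0.056 (LE) and -0.094 (HR). Mt2 (LE) was 0.0093 after quantile normalization and 3.43e-06 with the hybridisation covariate, and Nt5c3 (LR) 0.045 without the arrays that stood apart. Without these arrays 4 quality differences turned: Gapdh 3' minus 5' (HE) -0.024, relative log expression range -0.0080 (HE) and -0.027 (LR), and actin 3' minus 5' (LR) 0.0046.

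Pairing by replicate number stays open. In 0 of 15 pairs of groups, most of different mice, did all same-numbered arrays' deviations correlate over 0.1. Within a dose 3 of 7 control, 7 of 15 low-dose and 4 of 13 high-dose numbers did. A block by number within a dose had a consensus correlation of 0.0212. It gave 3 (HR) and 16 (IL) genes and 5 (LR) lists, keeping 65 of 80 named calls. Alas2 (LE) was 1.29e-05 and Mt2 (LE) 0.0055, not past the threshold.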

Other observations

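The tests named here of the high-minus-low difference across collections, and the count of shared signs, were chosen after the data were examined, while the gene lists and their tests were fixed before.

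Lists that were not shifted between the collections held single genes that changed in 1 direction at every dose, and none of those named was past the threshold in an interaction. Among 38 oxidative phosphorylation genes those that rose included Ndufv1 at 0.68, 0.64 and 0.72 in control, low-dose and high-dose mice, Ndufs7 at 0.63, 0.49 and 0.54 and Atp5d at 0.57, 0.49 and 0.52. The ATP synthase gene Atp5b fell at the low dose (-0.29) and was -0.22 in controls and -0.15 at the high dose (adjusted p = 0.0963 and 0.0897). Of these 38, 10 rose and 6 fell in controls (10 and 7 adjusted over the list alone), 15 and 12 at the low dose and 17 and 6 at the high dose (both as adjusted over the list alone), without a shift of the list (camera adjusted p = 0.388, 0.681 and 0.144). Of 24 NF-kappaB targets 7 rose and 1 fell in controls, 4 and 5 at the low dose, and 7 and 7 at the high dose (7 and 9 there adjusted over the list alone, otherwise as many), and the list was not shifted (0.329, 0.739 and 0.517). Those that rose at every dose included the signalling adaptor gene Traf1 (0.69, 0.68 and 0.82), the subunit gene Relb (0.66, 0.40 and 0.57) and the adhesion gene Icam1 (0.65, 0.36 and 0.38). Of 36 interferon response genes 9 rose and 2 fell in controls, 14 and 5 at the low dose (14 and 6 adjusted over the list alone, otherwise as many) and 15 and 2 at the high dose, among them Ifi35 (0.55, 0.55 and 0.61) and Parp14 (0.45, 0.45 and 0.42), again without a shift of the list (0.53, 0.681 and 0.146).

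Plasma cell and T cell lists held genes that moved in both directions between the collections. Of 9 plasma cell markers 4 rose and 1 fell in controls, 3 and 2 at the low dose and 4 and 1 at the high dose, as many as adjusted over the list alone (camera adjusted p = 0.388, 0.851 and 0.404). The B cell coactivator gene Pou2af1 rose by 0.95, 0.56 and 0.93 in control, low-dose and high-dose mice, while Sdc1, a surface marker of plasma cells, fell by 0.29 in controls and by 0.24 at the low dose and was -0.09 at the high dose, not past the threshold. Jchain, the joining chain of secreted antibodies, fell at the low (-0.57) and high dose (-0.58, adjusted p = 0.00491) and was -0.43 in controls (0.169). Of 26 T cell genes 4 rose and 3 fell in controls (4 and 2 adjusted over the list alone, otherwise as many), 8 and 3 at the low dose and 9 and 3 at the high dose. Among them Gimap3 (0.64, 0.48 and 0.59) and Thy1 (0.34, 0.39 and 0.49) rose and Trat1 fell (-0.68, -0.36 and -0.60), and the list as a whole was not shifted (0.846, 0.681 and 0.222). Of 24 neutrophil markers 6 rose and 1 fell in controls, 6 and 1 at the low dose (4 and 0 adjusted over the list alone, otherwise as many) and 10 and 0 at the high dose, Cd177 among them (0.64, 0.50 and 0.75), in a list that was not shifted (0.388, 0.472 and 0.299). Of 23 antioxidant genes 4 rose and 9 fell in controls (5 and 13 adjusted over the list alone, otherwise as many), 7 and 10 at the low dose and 7 and 9 at the high dose, without a shift of the list (0.14, 0.382 and 0.272). Gstp1 (0.35, 0.33 and 0.39) and Keap1 (0.33, 0.36 and 0.33) rose, and glutathione reductase, Gsr, fell (-0.63, -0.36 and -0.54).

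Counted over genes, 7748 changed between the collections at 1 or more of the 3 doses, 3339 of them at all 3 in one direction (2361 higher and 978 lower) and 0 at all 3 in differing directions.

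The difference between high and low dose itself changed between exposure and recovery for 8 genes, all lower after recovery and all among those called between the doses after exposure (limma, 554 genes at an unadjusted p under 0.05). They were the chaperone and co-chaperone genes Hspa1b (-1.73, adjusted p = 7.13e-07), Hsph1 (-0.89), Dnaja1 (-0.69), Stip1 (-0.64), Chordc1 (-0.51), Hsp90aa1 (-0.46) and Hspd1 (-0.44, 0.0286), and the myo-inositol transporter gene Slc5a3 (-0.80).

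Of the 2349 genes called between the doses after exposure, 2242 had after recovery the same sign of the difference between doses as after exposure, with medians of 0.11 and -0.11 for the higher and the lower genes. Genes are not independent replicates, and this count carries no test.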
